A study of Triticum aestivum with 8 samples.

How the data were processed

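Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in 4 tissues of hexaploid bread wheat (Triticum aestivum), cultivar AiKang58. The labels list 8 libraries, 2 per tissue. Leaves, roots and shoot apices came from 2-week-old seedlings grown with 16 h of light at 22 °C and 8 h of dark at 19 °C. Axillary buds of 1.0 to 2.0 cm came from 6-week-old plants that had spent 30 days at 4 °C, so tissue, age and cold differ together between the buds and the other tissues.

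For each tissue the authors deposited 1 peak list, which the labels of both libraries of that tissue cite. Each list holds a chromosome, a start and an end per peak and no height, score, p-value or read count. Reads were trimmed with Trimmomatic 0.36, and Bowtie2, MACS2 and bedtools were also used, per the submitters' processing notes. Versions of these other tools, the genome build, the peak threshold, and whether the 2 replicates were pooled before peak calling or their peaks combined afterwards are not given in the sources used here. Because the lists carry no value per library, no spread between replicates could be computed, and tissues were compared by a test only in how subgenome contrasts differ between 2 tissues, with chromosome groups as units. The sequencing depth behind each list is unknown. A longer list can reflect deeper sequencing as well as more open chromatin, and a position without a peak is not shown to be closed.

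The lists were checked to be sorted, free of repeats and of overlapping peaks, and to lie on 21 chromosomes named 1A to 7D, with no unplaced sequence. Starts were taken as counted from 0, as in BED files, and are printed counted from 1. Chromosome length was taken as the end of the last peak over the 4 lists (14065 Mb in all). A gene table of the assembly IWGSC CS RefSeq v2.1 was on hand. On each of the 21 chromosomes its last gene lies 0.169 to 21.9 Mb beyond the last peak. Only 3.53% of leaf peaks lie within 1 kb of an edge of a protein-coding gene in that table, against 3.32% after all peaks were moved by 1 Mb. The coordinates of the table therefore were not used, and no peak was assigned to a gene. Only its number of protein-coding genes per chromosome entered an alternative. The planned analyses of promoters, gene lists, homoeologous gene triads and sequence motifs need an annotation or sequence on the build of the peaks and were not run. For the same reason regions are named by position, by the rule fixed for this case before the data were examined: the 3 widest regions found in a single tissue for each tissue, the 5 widest regions shared by all 4, and for each tissue the 1 Mb window with most peaks. Windows, runs and chromosomes named beyond this rule were chosen after their values were seen, and the text says so.

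Peaks of different lists were counted as overlapping when they shared at least 1 bp. For each of the 6 pairs of tissues the share of the peaks of both lists that overlapped the other list was computed, with the Jaccard index (shared bases over all bases covered). The level of chance came from 100 random circular shifts of one list along each chromosome and, as an alternative added after seeing the data, from 100 shifts of 20 kb to 1 Mb, which keep the density along the chromosome. Overlapping peaks of the 4 lists were merged into 221805 regions, each classed by the set of tissues with a peak in it. A peak was called distal when its midpoint lay in the outer 20% of the chromosome length at either end. Shares carry 95% Wilson intervals, which cover counting error over peaks only.

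Peak density (peaks per Mb) was compared between the A, B and D subgenomes with an exact two-sided sign-flip permutation test of the mean difference over the 7 homoeologous chromosome groups. With 7 groups there are 128 sign patterns and the smallest p is 0.0156. The 12 tests (3 pairs of subgenomes in 4 tissues) were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The p-values measure the spread between chromosomes within a list, and chromosomes are not replicates of a tissue. The lowest and highest of the 7 chromosomes of each subgenome were checked as outliers by Dixon's test. Whether a difference between subgenomes differed between tissues was tested in the same way on log2 ratios of densities scaled to list size, 18 tests in all. Alternatives were the wider peaks alone (at least 507 bp, the median width of the 4 lists together), a reciprocal overlap of 50%, gaps of up to 500 bp counted as shared, regions assigned to a tissue only where it covers 50% of their bases, lists cut to 119387 peaks each, bases covered per Mb, peaks per protein-coding gene, outer 10% in place of 20%, and leaving out each homoeologous group in turn.

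The share of peaks in the outer 10% was also compared within 5 classes of width with about equal numbers of peaks of the 4 lists together and among the 30000 widest peaks of each list, both chosen after the data were seen. Runs of neighbouring regions found in a single tissue, or missing in a single tissue among the regions shared by the other 3, were compared with 100 random placements of the same regions within each chromosome, and missing shoot apex regions also with 1000. The step in density on chromosome 1B was placed where 2 Poisson rates over 1 Mb windows fitted the first 400 Mb best. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Functions were tested on simulated data. With a D density set 25% above A, the sign-flip test called D against A in 100 of 100 simulated lists on 21 chromosomes. It called B against A, with no difference set, in 3 of 100. Calls used an unadjusted p under 0.05, and all simulated chromosomes of a subgenome had the same set density. The spread between real chromosomes was not simulated, so these counts check the code and do not give the power of the test in these data.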

Results

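The data comprised 4 lists of accessible chromatin regions (ATAC-seq peaks) from leaves, roots, shoot apices and axillary buds of the wheat cultivar AiKang58, 1 list for the 2 libraries of each tissue. The series compares the regulatory landscape of these tissues in a genome with 3 related subgenomes, A, B and D. Shoot apices gave 131949 peaks, leaves 123032, axillary buds 122118 and roots 119387. The peaks covered 100.02 Mb in shoot apices, 94.3 Mb in axillary buds, 85.3 Mb in leaves and 79.4 Mb in roots, which is 0.711%, 0.6704%, 0.606% and 0.564% of the length of the 21 chromosomes. Median peak width was 500 bp in leaves and roots, 525 bp in shoot apices and 550 bp in axillary buds. Peaks of at least 2 kb made up 5.19% of the shoot apex list and 5.12% of the bud list, against 3.86% in leaves and 3.01% in roots. With 1 list per tissue, none of the differences between tissues given here has a replicate error.

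The first comparison asks which accessible regions the tissues share. The shoot apex list overlapped most with the other lists, and roots and axillary buds overlapped least. Leaves and shoot apices shared 65.4% of the peaks of both lists (95% interval 65.2 to 65.6), roots and shoot apices 62.3% (62.1 to 62.5), and shoot apices and axillary buds 60.8% (60.6 to 61.0). Leaves and roots shared 57.4% (57.2 to 57.6), leaves and axillary buds 55.3% (55.1 to 55.5), and roots and axillary buds 50.8% (50.6 to 51.0). Counted in bases, the Jaccard index was highest for leaves and shoot apices (42.0%), followed by shoot apices and axillary buds (39.9%), and lowest for roots and axillary buds (27.5%). Randomly shifted lists overlapped by 1.18 to 1.34% on average, and lists shifted by at most 1 Mb by 1.82 to 2.44%, and each pair lay above the highest of these shifts (2.61%). With a reciprocal overlap of 50% the shares were 29.3% (roots and buds) to 43.6% (leaves and shoot apices). The order below leaves and shoot apices depends on peak width. Among peaks of at least 507 bp, the median width of the 4 lists together, shoot apices and axillary buds shared 62.5% and roots and shoot apices 54.7%.

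Merging the 4 lists gave 221805 regions. Of these, 43661 (19.7%, 95% interval 19.5 to 19.9) had a peak in all 4 tissues and 100552 (45.3%, 45.1 to 45.5) in a single tissue. These classes rest on an overlap of 1 bp: where a tissue had to cover 50% of a region, regions of all 4 tissues fell to 16504, below the regions of each single tissue (24857 to 38442). Shared regions were wide, with a median of 1308 bp (quartiles 900 and 2000), and held 39.6% of the merged bases. Regions of a single tissue were narrow, with a median of 375 bp (quartiles 275 and 500), and held 24.5%. This contrast in width is in part built in by the merging. A region of a single tissue is 1 peak, while a region of all 4 tissues joins peaks of 4 lists. Wide peaks also overlap others more easily. Axillary buds had 31711 regions of their own (27.7% of bud regions, 27.4 to 27.9) and roots 26451 (23.5%, 23.2 to 23.7). Leaves had 22451 (19.7%, 19.5 to 19.9) and shoot apices 19939 (16.2%, 16.0 to 16.4). Of the regions open in the other 3 tissues, shoot apices lacked a peak at 5.54% (5.33 to 5.75). Leaves lacked a peak at 15.3% (14.99 to 15.6), roots at 20.7% (20.4 to 21.04) and axillary buds at 22.2% (21.8 to 22.5). Among regions found in exactly 2 tissues, leaves with shoot apices (9748) and roots with shoot apices (9667) were the most frequent pairs, and roots with axillary buds (3655) the least frequent.

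**Figure D1:**
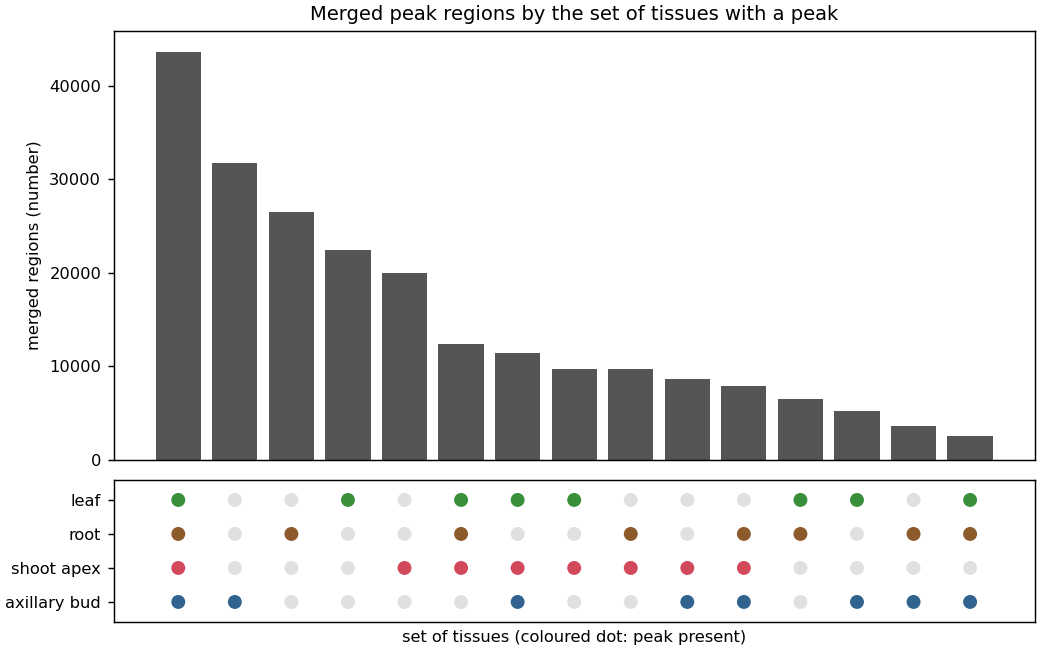
Number of merged peak regions (vertical axis) for each set of tissues, with coloured dots marking the tissues that have a peak. With an overlap of 1 bp, regions of all 4 tissues (43661) are the largest class (not so where a tissue must cover 50% of the region, 16504), followed by those of axillary buds alone (31711), and regions of leaves, roots and buds without shoot apices (2559) are the smallest.

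The widest regions of all 4 tissues lay on chromosome 6D from 5176529 to 5193318 (16790 bp), on 2A from 680350834 to 680364866 (14033 bp) and on 2B from 792984232 to 792998133 (13902 bp). The next lay on 1A from 588902753 to 588916634 (13882 bp) and on 2B from 367713084 to 367726658 (13575 bp). These regions join peaks of 4 lists, whereas a region of a single tissue is a single peak. Joining is not the whole reason for their width, because the widest single peak of each list had 12050 to 13669 bp. Regions of a single tissue did not exceed 6375 bp. That width was reached by a root region on 3B from 785546795 to 785553169. Other wide root regions lay on 4D from 459065644 to 459071743 (6100 bp) and on 3A from 717651058 to 717657007 (5950 bp). The widest leaf regions lay on 1B from 668243598 to 668249447 (5850 bp), on 2B from 679699564 to 679704838 (5275 bp) and on 3B from 730230636 to 730235771 (5136 bp). The widest bud region lay on 1B from 683094595 to 683100169 (5575 bp). A pair of neighbouring bud regions lay on 3A from 720839242 to 720843616 (4375 bp) and from 720844491 to 720849515 (5025 bp). The widest shoot apex regions lay on 1D from 382232891 to 382237965 (5075 bp), on 7A from 432973091 to 432977940 (4850 bp) and on 6A from 524309307 to 524313831 (4525 bp). All positions are those of the deposited lists, whose genome build is not given in the sources used here, and the genes at these positions were not looked up.

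Across the 13700 windows of 1 Mb with a peak in at least 1 tissue the median was 7 peaks in leaves and shoot apices and 6 in roots and buds. The window on 7D from 4000001 to 5000000 held most peaks in leaves (81), shoot apices (114) and axillary buds (105), and it held 75 in roots. In roots the densest window was on 2A from 16000001 to 17000000, with 86 peaks against 59 in leaves, 71 in shoot apices and 68 in buds. Some windows, chosen after their values were seen, differed most between tissues. On 2D from 9000001 to 10000000 roots had 52 peaks, against 12 in leaves, 18 in shoot apices and 22 in buds. On 1B from 689000001 to 690000000 buds had 63 peaks, against 6 in leaves, 19 in roots and 16 in shoot apices. On 5B from 691000001 to 692000000 leaves had 66 peaks and shoot apices 14, with 35 in roots and 45 in buds. On 6D from 7000001 to 8000000 roots had 18 peaks, against 47 in leaves, 44 in shoot apices and 47 in buds.

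The next comparison asks where along the chromosomes the peaks of each tissue lie. In all 4 tissues peaks were concentrated toward the chromosome ends, most in axillary buds and least in leaves. The outer 20% at each end held 67.7% of bud peaks (95% interval 67.5 to 68.0), 63.3% of root peaks (63.0 to 63.6), 61.9% of shoot apex peaks (61.7 to 62.2) and 58.2% of leaf peaks (57.9 to 58.5). On each of the 21 chromosomes the bud share was above that of the other 3 tissues and the leaf share below it. Single chromosomes ranged from 57.2 to 73.9% in buds and from 49.1 to 66.0% in leaves. The outermost 2.5% of the length at each end held 17.2% of bud peaks, 13.8% of root peaks, 12.5% of shoot apex peaks and 11.4% of leaf peaks. Regions of a single tissue differed more than whole lists. Of bud-only regions 72.6% (72.1 to 73.1) were distal, against 66.5% (66.0 to 67.1) of root-only, 60.3% (59.6 to 61.0) of shoot-apex-only and 50.7% (50.01 to 51.3) of leaf-only regions. Regions of all 4 tissues lay between these values, at 62.3% (61.9 to 62.8). Regions of roots, shoot apices and buds without leaves were the most distal class, at 77.5% (76.6 to 78.4). Regions of leaves, roots and shoot apices without buds were the least distal, at 48.4% (47.5 to 49.3).

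**Figure D2:**
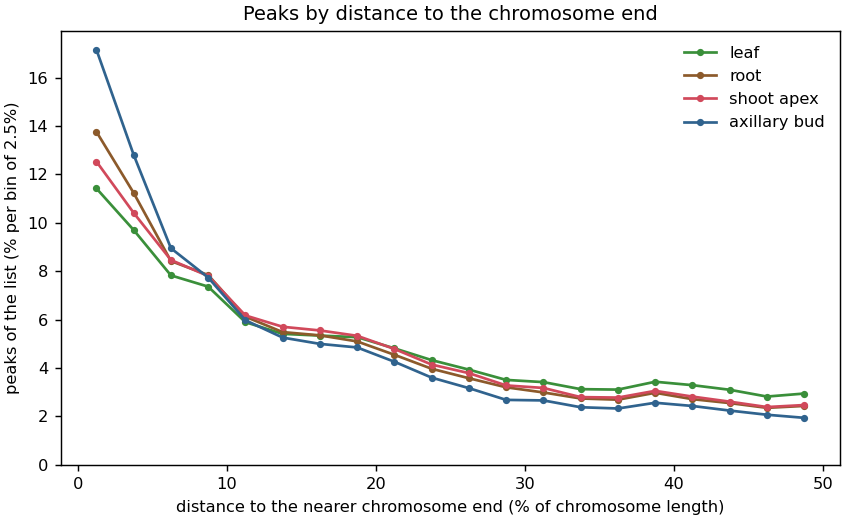
Share of each list's peaks (vertical axis, percent per bin of 2.5% of chromosome length) against the distance of the peak midpoint to the nearer chromosome end (horizontal axis, percent of chromosome length), 1 line per tissue over 21 chromosomes. In the outermost bin axillary buds lead with 17.2% and leaves are lowest with 11.4%, and near the chromosome middle leaves lie above buds.

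The third comparison asks whether accessible regions are spread evenly over the 3 subgenomes. Each subgenome held about as many peaks as the others: A had 33.2 to 33.9% of the peaks of a list, B 32.5 to 33.2% and D 33.5 to 34.2%. The D subgenome is the shortest, with 28.1% of the length against 35.1% for A and 36.8% for B, and its peak density was the highest in all 4 tissues. In leaves D chromosomes carried 10.4 ± 0.69 peaks per Mb (SD, n = 7 chromosomes), A chromosomes 8.41 ± 0.67 and B chromosomes 7.76 ± 0.88. In roots the densities were 10.3 ± 0.91 for D, 8.02 ± 0.77 for A and 7.47 ± 0.88 for B. In shoot apices they were 11.2 ± 0.70 for D, 9.07 ± 0.87 for A and 8.25 ± 0.88 for B, and in axillary buds 10.4 ± 0.74 for D, 8.20 ± 0.61 for A and 7.81 ± 0.95 for B. D exceeded A by 23.5 to 28.1% and B by 33.0 to 37.5%, in 7 of 7 homoeologous groups in each tissue. These 8 differences passed the exact sign-flip permutation test (p = 0.0156 each, the smallest the 7 groups allow, Benjamini-Hochberg adjusted p = 0.0234 over 12 tests).

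The difference between A and B did not pass the exact sign-flip permutation test over the 7 groups in any tissue. In roots it passed the same exact permutation test with group 6 left out (0.81 peaks per Mb, adjusted p = 0.0417). That pass adds no support: group 6 was the only group of roots with B above A (6.62 peaks per Mb on 6A, 7.65 on 6B). Without it all remaining groups had the same sign, so the test had to give its smallest p. Mean A minus B differences were 0.64 peaks per Mb in leaves, 0.55 in roots, 0.82 in shoot apices and 0.40 in buds. Without group 1 they were 0.27, 0.25, 0.43 and 0.036. The exact permutation p-values were 0.141, 0.203, 0.0781 and 0.484, with adjusted values of 0.169, 0.222, 0.104 and 0.484. A was denser in 5 of 7 groups in leaves, shoot apices and buds and in 6 of 7 in roots. None of the 18 differences of a subgenome contrast between 2 tissues passed the exact sign-flip test after adjustment (smallest adjusted p = 0.321, smallest exact p = 0.0312, for B against D in leaves and roots). Of these 18, 2 had an unadjusted p under 0.05. With 7 groups a lone difference among 18 cannot have an adjusted p below 0.281, and 6 at the smallest p would be needed to pass, so this family says little about the absence of such differences.

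The D excess was a density per length. Per protein-coding gene of the gene table, leaves had 1.254 ± 0.06 peaks on A, 1.15 ± 0.14 on B and 1.22 ± 0.06 on D chromosomes (SD, n = 7), and axillary buds 1.22 ± 0.03, 1.16 ± 0.15 and 1.22 ± 0.06. In roots the means were 1.19, 1.11 and 1.21, and in shoot apices 1.35, 1.22 and 1.32. No pair of subgenomes passed the test on this scale in any tissue (adjusted p from the exact permutation test 0.281 to 0.828). The D mean stayed above the B mean in each tissue, with B above D in 2 of 7 groups, so an excess of D over B is not shown to be absent. The gene numbers come from another assembly than the peaks.

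**Figure D3:**
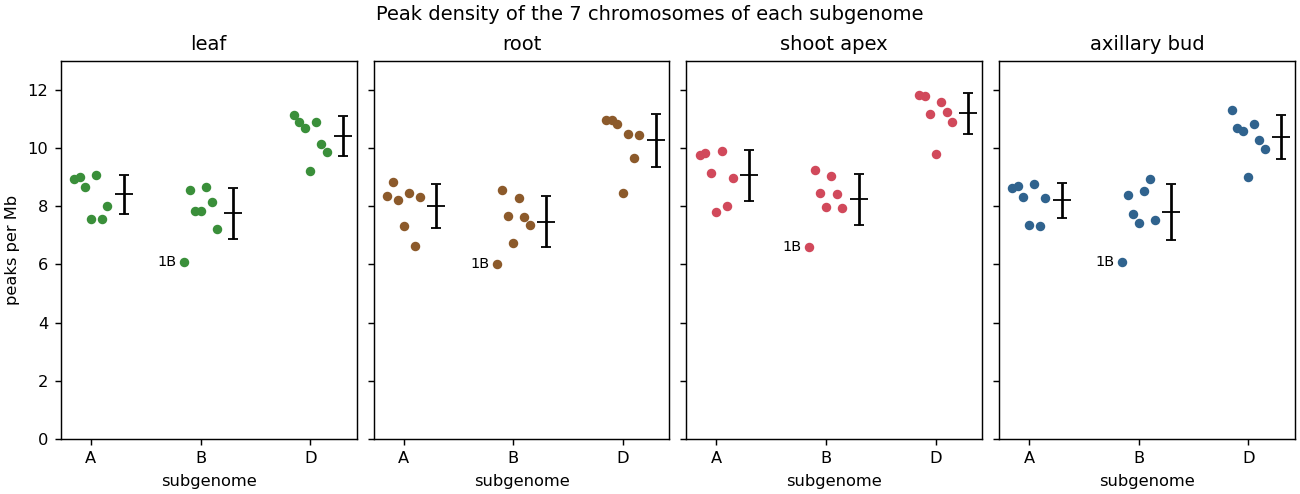
Peaks per Mb of chromosome length (vertical axis) for the 7 chromosomes of each subgenome (points, in the order of groups 1 to 7 from left to right), with mean and SD over 7 chromosomes (black bars), 1 panel per tissue. D chromosomes have the highest mean in each panel, and 1B is the lowest B chromosome, at 6.02 to 6.60 peaks per Mb.

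Chromosome 1B had the lowest density of all 21 chromosomes in each tissue, at 6.09 peaks per Mb in leaves, 6.02 in roots, 6.60 in shoot apices and 6.07 in axillary buds. As a whole chromosome it was no outlier among the 7 B chromosomes by the Dixon test (gap over range 0.276 to 0.509, critical value 0.568), and neither was any other chromosome within its subgenome. The deficit was strongest in the first part of the chromosome, up to 245 Mb in leaves and roots, 248 Mb in shoot apices and 240 Mb in buds. Up to that position 1B had 1.34 peaks per Mb in leaves, against 6.72 on 1A and 8.45 on 1D over the same share of their length. The corresponding densities were 1.33, 6.37 and 8.35 in roots, 1.06, 6.499 and 8.29 in shoot apices, and 1.04, 5.82 and 8.53 in buds. Beyond it 1B had 0.763 to 0.786 of the mean density of 1A and 1D, also below the lowest of the other 6 groups in each tissue (0.806 to 0.836). In the first 60 Mb of 1B there were 134 leaf, 142 root, 111 shoot apex and 133 bud peaks, where the lowest of the other 6 B chromosomes had 460, 537, 478 and 503. With the first 240 Mb of 1B and the same share of the length of 1A and 1D left out, an alternative added after seeing the data, D still exceeded B by 2.41 to 2.78 and A by 2.03 to 2.30 peaks per Mb (adjusted p = 0.0234, exact sign-flip test).

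**Figure D4:**
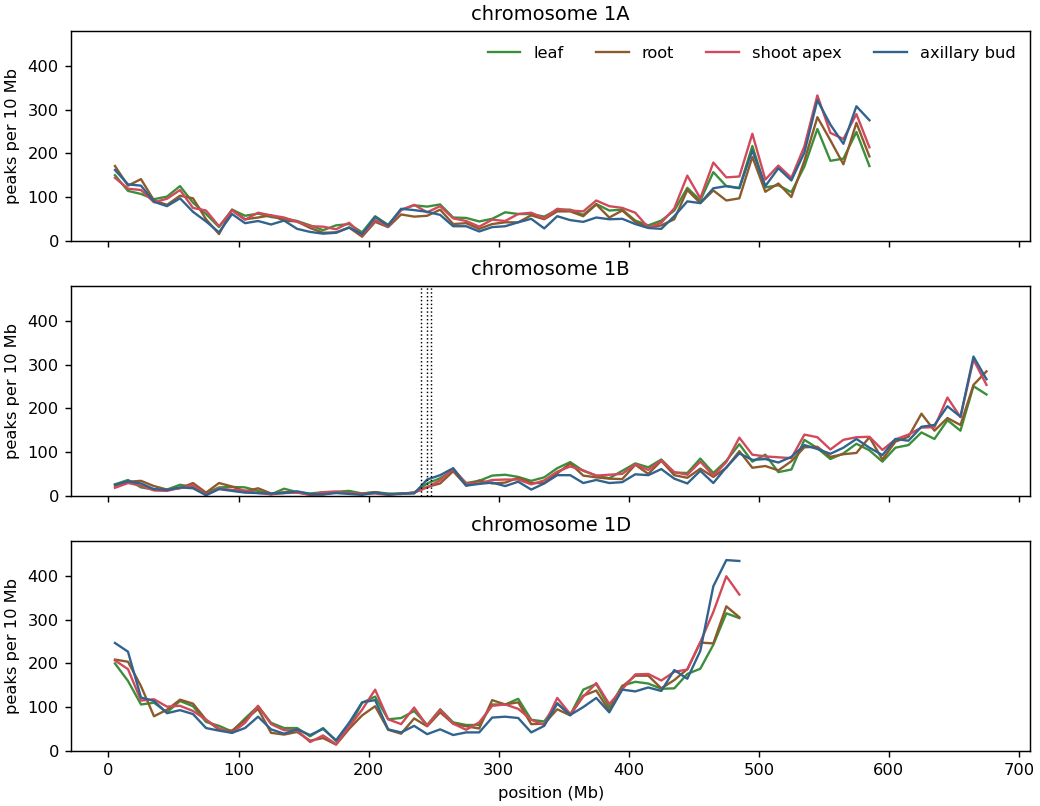
Peaks per 10 Mb (vertical axis) along chromosomes 1A, 1B and 1D (horizontal axis, Mb), 1 line per tissue, with dotted lines at the best step in density on 1B. In all 4 tissues the 1B lines stay near the floor up to 240 to 248 Mb and rise beyond it, while 1A and 1D carry many peaks at their start.

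Chromosome shares also differed between tissues, without a test because each tissue has 1 list. The chromosomes named here were chosen after their values were seen. Axillary buds had 6451 peaks on 6B, a share of the list 13.2% above the mean share in the other tissues. Roots had shares 7.43% above the other tissues on 7D, with 6678 peaks, and 5.40% above on 3D. Root shares were 8.8% below the other tissues on 6A and 8.7% below on 4B. Leaves had a share 7.53% above on 4B, with 5280 peaks. The leaf and root values on 4B are not independent, because each is set against a mean that includes the other tissue.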

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

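Leaving out the first part of group 1, the shifts of at most 1 Mb and the step on 1B were chosen after the data were seen. No paired analysis was possible because the lists carry no value per library, and leaving out each replicate was not run for the same reason. The planned analyses of promoters, gene lists, triads and motifs, and densities over a chromosome length from a reference, were not run. Depth is unknown, so it limits every comparison of list sizes. The numbers of regions of 1 tissue stayed within 1.5 times under the 3 alternatives run for them, while regions of all 4 tissues fell to 16504 where a tissue had to cover 50% of the region. Bud-only regions stayed the most numerous, but their lead over root-only regions varied. The numbers were 23245 and 22126 with gaps of up to 500 bp counted as shared. They were 31790 and 29050 in lists cut to the same number of peaks, and 38442 and 30751 with 50% of the region covered. Peaks of at least 507 bp numbered 58718 in leaves, 56437 in roots, 67947 in shoot apices and 65174 in buds. Among these the shared shares were 63.9% for leaves and shoot apices, 62.5% for shoot apices and buds, 54.7% for roots and shoot apices, 54.6% for leaves and buds, 54.1% for leaves and roots and 48.3% for roots and buds. With a reciprocal overlap of 50% they were, in the same order, 43.6%, 38.5%, 43.2%, 31.8%, 38.4% and 29.3%, so roots and buds stayed lowest and leaves and shoot apices highest. The cause of the change in order with peak width was not tested. The distal shares kept their order among peaks of at least 507 bp (leaves 58.9%, shoot apices 63.1%, roots 65.3%, buds 69.5%) and in the outer 10% (36.3%, 39.2%, 41.3% and 46.6%). The D excess per Mb held for bases covered, for peaks of at least 507 bp, without the first part of group 1 and without each homoeologous group. Leaving out a group adds no separate support here. D was above A and B in 7 of 7 groups, so the test had to pass whichever group was left out. Without group 6 the A excess over B in roots passed the threshold (0.81 peaks per Mb, adjusted p = 0.0417, exact sign-flip test). This adds no support either, because group 6 was the only group of roots with B above A, so its omission fixed the outcome. Over the 7 groups left out in turn the A minus B difference in roots ranged from 0.25 to 0.81 and its adjusted p from 0.0417 to 0.443. The corresponding ranges were 0.27 to 0.85 in leaves, 0.43 to 1.03 in shoot apices and 0.036 to 0.73 in buds, each lowest without group 1 and highest without group 6, and the cause was not tested. Per protein-coding gene no difference with D passed the exact sign-flip test. The D mean stayed above the B mean in each tissue, while it was above the A mean only in roots. A minus D became 0.029 peaks per gene in leaves, 0.034 in shoot apices and 0.0025 in buds, and was -0.013 in roots. B minus D was -0.072 in leaves, -0.10 in roots, -0.094 in shoot apices and -0.061 in buds. The change from the D excess per Mb follows from the number of genes per chromosome, which is about equal between subgenomes of unequal length.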

Other observations

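The tests on chromosome 1B, on bud peaks by width, on random placement of the 5A run and on peaks of other tissues within it were chosen after their results were seen, and so were the runs and the windows on 6B. Regions of a single tissue formed runs along the chromosomes. The longest root run was 16 neighbouring regions on 7B from 673971275 to 674146575, with 16 root peaks and none in the other tissues, where 100 random placements gave at most 7. The longest leaf run was 12 regions within 29.7 kb on 4A from 602619647 to 602649363, against at most 8. Shoot apices had no run of their own above 6 regions, against at most 7. Roots lacked 13 regions in a row that the other 3 tissues shared on 5B from 528936383 to 529611418, against at most 8. That span was not empty of root peaks: it held 5 at other regions, against 19 in leaves, 23 in shoot apices and 16 in buds. The longest runs of missing regions in leaves (8, on 7D) and buds (12, on 1B from 677120986 to 678255371) equalled the highest of the 100 random placements and lay above their 99th percentile (7.01 and 10.02). Their spans held 6 leaf and 8 bud peaks at other regions.

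Chromosome 6B carried more of the bud list than of the others. Its first 100 Mb had 1754 bud peaks against 1273 in leaves, 1449 in roots and 1476 in shoot apices. The bud share there was 28.0% above the mean of the other tissues, against 8.51% on the rest of 6B. Over the first 100 Mb of 6A and 6D it was 6.37% and 10.2% above. Of the 6B regions in this part 622 were found in buds alone, beside 1754 bud peaks. The first 100 Mb of 6A held 324 such regions beside 1028 bud peaks, and that of 6D 485 beside 1481. Bud-only regions were therefore not particular to 6B. Stretches over 1 Mb without a peak in any tissue numbered 918. The longest was 4.47 Mb, on 3A from 252192643 to 256662560.

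The first part of chromosome 1B was poor in peaks in all 4 tissues. General sparsity of peaks toward the centromere is argued against, because the deficit includes the chromosome end: the first 60 Mb of 1B held at most 0.291 of the peaks of the lowest other B chromosome. A tissue-dependent state of the arm is argued against by the share of 1B peaks before the step, which differed 1.37-fold between tissues (5.76 to 7.88%). DNA of the sampled plants that the reference does not hold on this arm is a candidate explanation. The density before the step was at most 0.181 of the mean of 1A and 1D, against at least 0.543 in the other groups, and the step lay within 8 Mb in all 4 tissues. A shared step would go with any cause common to the 4 tissues, so it does not favour this one. The explanation also requires a reference other than AiKang58, and the build is not given in the sources used here. As background from outside these data, AiKang58 is described as carrying a rye arm in place of the short arm of 1B. The first form of this test also required the rest of 1B to lie inside the range of the other groups, and by that form the result spoke against the explanation: the rest of 1B had at most 0.786 of the mean of 1A and 1D, against at least 0.806 in the other groups. The requirement was split off after that result was seen, since a replaced arm makes no prediction for the other arm. The lower density of the rest of 1B is left unexplained, and no biological explanation for that part was tested.

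Bud peaks lay nearer to chromosome ends than those of the other tissues, with 46.6% in the outer 10% at each end, 5.39 percentage points above roots. Wider peaks in the bud list are argued against as the whole cause: within 5 classes of peak width the bud share exceeded the highest other share by at least 3.69 points. An excess of narrow peaks in a longer bud list is argued against too. The bud list (122118 peaks) was shorter than those of leaves and shoot apices. It had the fewest peaks of all lists in each of the narrowest classes of width (21117 and 20833). Whether the bud list was called less strictly cannot be tested by width, because the lists hold no score. Among the 30000 widest peaks of each list the bud share was 51.6%, 6.78 points above roots. With each list limited to its 119387 widest peaks the difference was 5.45 points, which decides nothing because only 2731 bud peaks were removed. The shift was not carried by a few chromosomes: it was present on 21 of 21. Tissue, age and cold of the bud plants cannot be told apart, because the buds came from older plants kept in the cold. Differences in library quality stay open as well, because the lists carry no reads.

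On chromosome 5A, 34 neighbouring regions from 2365143 to 2880527 had bud peaks and 0 peaks in leaves, roots or shoot apices. Random placement of bud-only regions, with all regions of a chromosome equally likely, is argued against: the longest run in 100 placements was 9. The longest bud-only run on another chromosome was 15, on 6B from 8047 to 135429. A general excess of bud-only regions near this end was not decided: 64.3% of the bud regions in the 500 kb on both sides were bud-only, 0 of 10 before the run and 27 of 32 after it, against 30.7% in the outer 10% of 5A. DNA present in the bud plants and missing or diverged in the other plants may also give such a block, and the 0 peaks of the other tissues do not decide it because the span was chosen for them. Tissue, age and cold of the buds stay open as untested biological differences.

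A further hypothesis was that blocks of DNA are missing or diverged in the plants of the shoot apex libraries, raised by windows with few shoot apex peaks. A shallower or stricter shoot apex list is argued against, since shoot apices lacked 5.54% of the regions of the other 3 tissues, the lowest share of the 4. The longest run of missing shoot apex regions was 6, on 4B from 291818858 to 291837837, and 1000 random placements gave at most 5. By the rule set beforehand this spoke against scattered misses that fall together by chance, by a margin of 1 region. The placements took all regions as equally likely to be missed, whatever their width. Regions of this run were narrow, with a median of 331.5 bp. All regions of leaves, roots and buds without shoot apices had a median of 895 bp. Chance is therefore not decided. That run held 0 shoot apex peaks, against 10 in leaves, 7 in roots and 8 in buds, which cannot decide for missing DNA because the span was chosen for lacking them. The hypothesis stays open.

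It was also asked whether regions of a single tissue fall on the subgenomes otherwise than regions of all 4 tissues. No adjusted p over 12 exact sign-flip permutation tests was under 0.05 (smallest 0.188, with 3 unadjusted values under 0.05). In buds the log2 ratio of bud-only to shared regions was lower on A than on B by 0.14 (SD 0.07, 7 of 7 groups, exact p = 0.0156), which did not pass the correction. With 7 groups a lone difference among 12 cannot have an adjusted p below 0.188, and 4 at the smallest p would be needed, so the question stays open.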
